A study of Corynebacterium glutamicum R with 10 samples.

How the data were processed

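SigH-FLAG binding was measured on 10 Agilent 2-colour arrays, 3 for each phase of the rshA deletion strain and 2 for each phase of the wild type, described in the series as biological replicates. Per the labels' protocols, cells grew at 33 °C in rich medium with 1% glucose, were fixed with 1% formaldehyde for 20 min, and their DNA was sheared to an average of 600 to 1000 bp. Chromatin was precipitated with an anti-FLAG antibody, and a portion of the lysate was kept as reference DNA. Both kinds of DNA were joined to linkers and amplified by PCR before labelling, with Cy5 for ChIP and Cy3 for reference DNA on every array, so there were no dye swaps and a dye bias of a probe would stay in its ratio. Groups and replicate numbers came from the sample titles.

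The scanner output of each array gave intensities, which per the file headers were extracted with Agilent Feature Extraction 10.5.1.1. The processed intensities are background-subtracted and dye-normalized, with linear and LOWESS factors per the file headers. Median spot intensities and local background intensities are deposited as well, without correction, and the mean intensities were not used here. The log10 ratio per the file headers is the ratio of the processed red and green intensities and was not used further. The authors' deposited value table gave log2 ratios for 36911 tiling probes. They equalled log2 of processed red over processed green signal on every array within 5e-10, so scale and direction are known, and their medians lay between -0.0529 and 0.00890, so the authors had not centred them further. The table was used as an alternative, without removal of non-uniform spots. No aligner, peak caller or genome build is given in the sources used here.

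The enrichment of a probe was log2 of processed ChIP over processed reference signal, averaged over the spots of the probe and centred on the median of all non-control probes of the array, with no loess or quantile step. Spots marked non-uniform in either channel and control spots were left out. Normexp proved unusable as an alternative, because it took most of the signal of these bright arrays for background. The deleted probes were left out of the ratio because a deleted sequence has no reference signal to divide by, a choice made after seeing the data. Each array held 43803 non-control spots. The main measurement used the 18462 forward tiling probes, and the 18449 reverse tiling probes, 3278 gene-numbered probes and 15 probes named CGRic were examined separately.

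The files give no coordinates, sequences or gene names for the probes, and a table of reference genes of another strain of the species shared no locus tags with them. Probes and regions are therefore given by their IDs, few of them, and no gene is named. The order of the forward probes along the chromosome was taken from their numbers. Neighbouring forward probes correlated with r = 0.734, and probes 3 numbers apart with r = 0.337, across probes. The reverse probes were numbered in the opposite direction (r = 0.514 in opposite order at the best shift and r = -0.00336 in the same order). The planned running mean over a window in base pairs could not be set without coordinates and was replaced by a mean over 3 probes (1 on each side). The planned tests of 14 gene lists at bound regions, of shifts of those lists and of a SigH promoter motif at the summits were not run, because they need gene positions and sequence. The rule for named genes had the same need. In its place the text names the deleted probes, the region with the highest mean and the region with the largest relative rise in the wild type in stationary phase, the last chosen after its values were seen.

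A bound region was a run of at least 3 forward probes whose mean over the 4 group means was at least 1 log2 unit with an adjusted p below 0.05 against 0, by limma 3.58.1 (lmFit, eBayes) in R 4.3.3 with Benjamini-Hochberg adjustment over all forward probes. Regions were set over all arrays so that differences between groups were not tested on regions picked in a single group. The mean over groups can still be carried by the deletion strain, since by size alone the wild type gave 3 regions in exponential and 12 in stationary phase. The set thus leans towards regions that are high in the deletion strain. The value of a region on an array was the mean of the summit probe and its neighbours, and fold values are powers of 2 of such log2 means. Contrasts between strains and phases were fitted by limma over the 27 regions, with all 10 arrays sharing the estimate of the spread. The fit took a common variance for all regions, and the regions of an array rose and fell together, so the regions are not independent of each other. The limma counts and p-values thus draw precision from regions that are not replicates, and they overstate the evidence of 10 arrays. Array medians were therefore tested too, by exact two-sided permutation. The region calls and contrasts were tested on simulated data with 200 regions and normal noise, independent between probes and scaled to the residual spread of each array. All regions of height 2 or 3 log2 units were called (100%), 0 regions were called where none was simulated, and none of those with a height of 1 and no strain change were called. For the strain contrast averaged over phases, 100% of simulated changes of 1 and of 2 log2 units passed, as did 5.97% of unchanged regions. The simulation holds independent probe noise only. It lacks the differences in yield between real arrays and any correlated noise between neighbouring probes or regions, so its rates may not hold for the real arrays. Equal replicate numbers in the titles were not taken as pairs. The check used the deviations of each array from its group mean, not the profiles themselves. Between arrays with equal numbers these deviations correlated by 0.367, 0.0291 and 0.256 across forward probes in the deletion strain, so 1 pair was not above 0.1. Against that, the values across the 27 regions were 0.666, 0.167 and 0.140. The wild type gave 0.474 (0.721 across regions), a single value, since with 2 arrays per group both pairs give the same. By these deviations, each exponential array of the deletion strain correlated best with the stationary array of its own number, a hint of pairing.

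Alternatives were normexp on the median signals (offset 50, in place of the mean signals), loess within arrays, the deposited table, removal of dim probes, no running mean or a mean over 5 probes, other region thresholds, values over whole regions, scaling of arrays to one median region (log2 values divided by the array median), other variance models, regions of single groups, slide or replicate number as a block, and leaving out each array. These alternatives were chosen before the data were examined. On arrays scaled to one median, the divided values were multiplied by the mean of the array medians. Differences on them are given in scaled log2 units and are not fold changes. Added later were raw signals at the deleted probes, no dye normalization, the reverse tiling, deleted probes kept, the share of summed excess enrichment (with excess below 0.05 set to 0.05), and the removal of deletion, stationary replicate 2 together with wild type, stationary replicate 1.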

Results

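Binding of the sigma factor SigH was mapped by chromatin immunoprecipitation on tiling arrays (ChIP-chip) in the soil bacterium Corynebacterium glutamicum R. SigH is an alternative sigma factor, the subunit that directs RNA polymerase to promoters, and is known for its role in the response to oxidative and heat stress. The rshA gene encodes its anti-sigma factor, a protein that binds SigH and holds it away from the polymerase. SigH carried a FLAG tag in a wild-type and in an rshA deletion background, and each strain was sampled in late exponential phase (OD610 up to 2.5) and at the onset of stationary phase (OD610 up to 7.0). The deletion strain had 3 arrays in each phase and the wild type 2, which made 10 arrays in 4 groups. On each array, immunoprecipitated DNA labelled with Cy5 was hybridized together with reference DNA that had not been immunoprecipitated, labelled with Cy3.

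All arrays were bright. The median spot had a raw reference signal between 31883 and 45421 and a raw ChIP signal between 74902 and 95704, 0 spots were saturated, and at least 99.8% of spots lay well above background in either channel. The arrays came from 4 slides. Slide 1 held 1 array of every group, slide 2 held 4 arrays of the deletion strain (2 per phase), and slides 3 and 4 held 1 wild-type array each. The number of arrays limits the precision of each value.

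The deleted gene was examined first, because it checks the strain labels. Exactly 3 probes had a reference signal at least 2 log2 units lower on every deletion array than on every wild-type array, and 0 probes had the opposite pattern. They were the forward tiling probe CGRfwd05404, the gene-numbered probe CGR0950 and 1 reverse tiling probe. Their mean reference signal was -7.94 ± 1.52 log2 units relative to the array median in the deletion strain (SD, n = 6) and -0.45 ± 0.13 in the wild type (n = 4), a difference of -7.49. No p is given for it, since the probes were picked for this difference. In the ChIP channel the values were -6.52 ± 2.24 and -0.08 ± 0.21. All 3 probes were not well above background in the reference channel on 4 of the 6 deletion arrays and were above it on the other 2, so the size of the difference is imprecise. In the raw signals, with no background or dye correction, it was -6.76. The files pair no probe with rshA, so the probes were found from their signal. The 4.90 log2 units that separated the strains at the weakest of the 3 compared with 0.75 at the next probe, and only 1 of the 210 splits of the arrays into 6 and 4, the split by strain, gave any such probe.

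SigH occupied a limited number of places on the chromosome. Over all 10 arrays, 27 bound regions of 3 to 6 consecutive forward probes passed the region rule (limma, adjusted p from 0.000253 to 0.00256 at the summits), with a mean enrichment over the 4 groups of 1.23 to 3.32 log2 units. The highest mean was at CGRfwd11098, where the centred ratio of ChIP to reference signal was 24.1-fold in the deletion strain in exponential phase and 3.71-fold in the wild type in that phase. A region of 3 probe positions, with a mean of 1.499 log2 units, covered the place of the deleted forward probe, where the value was taken from its neighbours alone. The reverse tiling, a separate set of probes, gave 25 regions, and 23 of the 27 forward regions had a reverse region within 4 probes. Calls within single groups were 38 regions in the deletion strain in exponential phase and 49 in stationary phase, and both sets included all 27. The wild type gave 0 regions in either phase by limma with 2 arrays each. At an unadjusted p under 0.05 the wild type gave 2 regions in exponential and 11 in stationary phase, and by size alone 3 and 12. Without deletion, stationary replicate 2, the wild type gave 12 regions in stationary phase, and the deletion strain gave 22 and 13 in exponential phase without its exponential replicates 2 and 3.

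**Figure D1:**
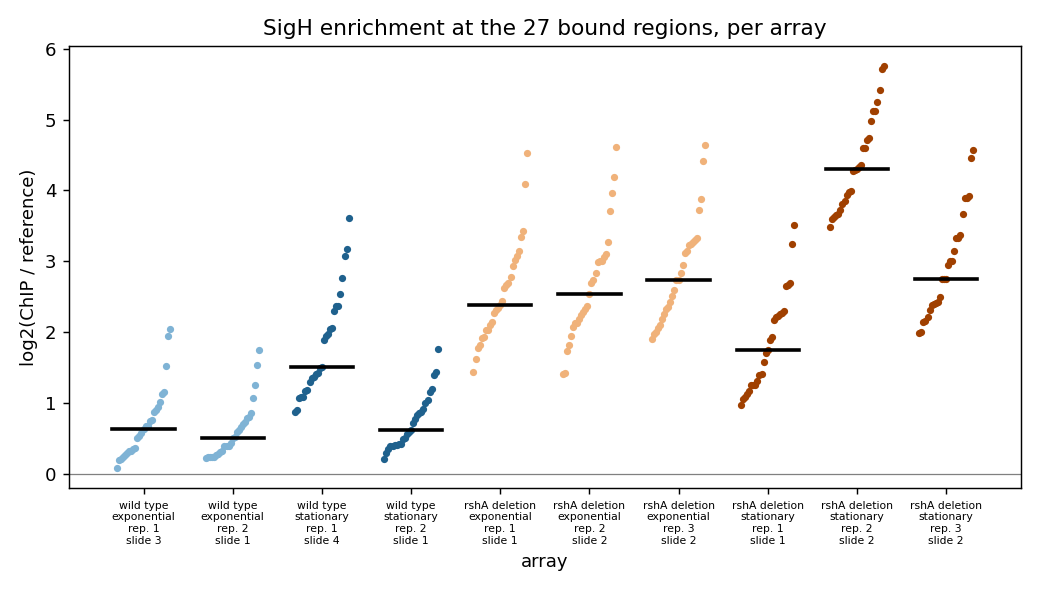
Each point is the log2 ratio of ChIP to reference signal (vertical axis) at 1 of the 27 bound regions on 1 array (horizontal axis, by group, replicate and slide), and the black bar is the median of the array. The medians lie between 1.74 and 4.30 on the 6 deletion arrays and between 0.50 and 1.51 on the 4 wild-type arrays.

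The comparison of strains asked how much SigH binding changes without its anti-sigma factor. Before scaling of the arrays, SigH enrichment was higher in the rshA deletion at nearly all bound regions in both phases. In exponential phase the median region was enriched by 2.55 ± 0.18 log2 units in the deletion strain (SD, n = 3) and by 0.56 ± 0.09 in the wild type (n = 2), or 5.87-fold against 1.48-fold. In stationary phase it was enriched by 2.93 ± 1.29 (n = 3) and 1.06 ± 0.62 (n = 2), or 7.62-fold against 2.09-fold. Most of the difference lay in the reference channel. The raw reference signal at the summits was -2.11 ± 0.19 log2 units relative to the array median in the deletion strain and -0.56 ± 0.06 in the wild type in exponential phase, and the raw ChIP signal 0.55 ± 0.10 and 0.08 ± 0.09 (SD, n = 3 and 2). In stationary phase the reference values were -2.53 ± 1.11 and -1.01 ± 0.62 and the ChIP values 0.67 ± 0.23 and 0.38 ± 0.35. Averaged over both phases, all 27 regions were higher in the deletion strain, by a median of 1.87 log2 units (3.66-fold). A rise shared by the regions cannot be told here from a higher yield of the immunoprecipitation on the deletion arrays, which was not tested for the strain difference.

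By limma, 26 of the 27 regions passed in exponential phase, with a median difference of 1.96 log2 units and a range of 1.25 to 2.78, and 23 passed in stationary phase, with a median of 1.76 and a range of 1.33 to 2.30. In each phase 0 were lower. The average over phases gave adjusted p-values from 0.000132 to 0.00953. Such counts and p-values pool the spread over regions that rise and fall together, so they overstate the evidence. The array medians of the strains did not overlap when all 6 deletion arrays were set against all 4 wild-type arrays (exact two-sided permutation test, p = 0.00476, the smallest possible). That test takes no account of slides, of which only slide 1 held both strains. Within a phase the exact permutation test gave p = 0.1 in exponential and p = 0.2 in stationary phase, where 3 arrays against 2 cannot go below 0.1. At CGRfwd11098 the enrichment was 4.59 ± 0.06 log2 units in the deletion strain and 1.89 ± 0.21 in the wild type in exponential phase (n = 3 and 2, limma adjusted p = 0.00402), and 4.56 ± 1.11 and 2.26 ± 1.15 in stationary phase (limma adjusted p = 0.0246). The largest difference in exponential phase was at CGRfwd14669, with 3.00 ± 0.34 against 0.22 ± 0.01 log2 units (limma adjusted p = 0.00402), and its stationary values were 3.68 ± 1.43 against 1.600 ± 1.09 (limma adjusted p = 0.0246). The region over the deleted probe had 2.23 ± 0.11 against 0.46 ± 0.10 in exponential phase (limma adjusted p = 0.0247) and 2.43 ± 1.20 against 0.88 ± 0.67 in stationary phase (limma adjusted p = 0.0490). The difference between the 2 strain effects was itself tested, and 0 of 27 regions passed (limma, 0 at an unadjusted p under 0.05, median -0.21).

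Within slide 1, all 27 regions were higher on the deletion array, by a median of 1.88 log2 units in exponential and 1.17 in stationary phase. With slide as a fixed block the median differences were 1.297, 1.605 and 1.499 in exponential phase, stationary phase and their average, and 0 regions passed in each (limma, 1, 1 and 12 at an unadjusted p under 0.05). With slide as a random block 22, 11 and 27 passed. In a fit to the stationary groups alone 0 of 27 passed (limma, 5 at an unadjusted p under 0.05). Without wild type, exponential replicate 1 or replicate 2, 0 regions passed in exponential phase, and 17, 10 and 11 passed without deletion, exponential replicate 1, 2 and 3. In stationary phase 0 passed without deletion, exponential replicate 1 or 2, deletion, stationary replicate 3, wild type, exponential replicate 2 or wild type, stationary replicate 2, while 10, 9 and 7 passed without deletion, exponential replicate 3, deletion, stationary replicate 2 and wild type, exponential replicate 1. Without deletion, stationary replicate 2, the median difference in stationary phase was 1.16, and that of CGRfwd14669 was 1.36. Without wild type, stationary replicate 2, that of CGRfwd11098 was 1.49 and that of CGRfwd14669 was 1.31. With dim probes removed, the strain difference of CGRfwd11098 was 2.21 in exponential and 1.67 in stationary phase, in place of 2.70 and 2.30. Both still passed (limma adjusted p = 0.00861 and 0.0401). That of CGRfwd14669 was then 2.61 and 2.05, in place of 2.78 and 2.08. In stationary phase 20 of 26 regions passed without dim probes. When the log2 values of every array were divided to give the same median region, which lowers strong regions of arrays with a high median, 8 regions were higher and 9 lower in exponential phase, 5 and 9 in stationary phase, and 8 and 11 on average. CGRfwd11098 was then lower in the deletion strain, by -3.09 and -1.03 scaled log2 units in the exponential and stationary phase. CGRfwd14669 differed by -0.35 in stationary phase, which did not pass. These are not fold changes, since in exponential phase CGRfwd11098 stood at 1.80 array medians in the deletion strain and 3.37 in the wild type. As shares of the summed excess enrichment of an array, 6 regions were higher and 2 lower in exponential phase, 5 and 0 in stationary phase, and 9 and 4 on average, and CGRfwd11098 differed by -0.19, 0.21 and 0.01 log2 units, none of which passed (limma adjusted p = 0.451, 0.374 and 0.956).

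**Figure D2:**
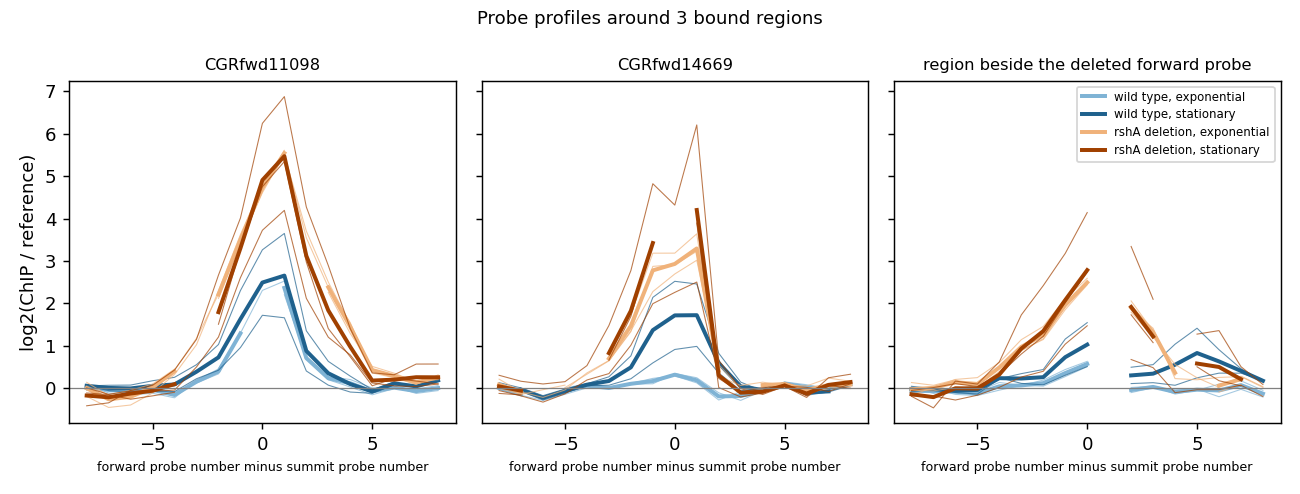
Log2 ratio of ChIP to reference signal (vertical axis) at the forward probes around 3 bound regions, numbered from the summit probe (horizontal axis). Thin lines are single arrays, thick lines are group means, and gaps are spots left out as non-uniform or as deleted. Before any scaling of the arrays, the deletion strain lies above the wild type at each summit. Its exponential means are 4.59, 3.00 and 2.23 log2 units over the summit and its neighbours, against 1.89, 0.22 and 0.46. Scaling to the same median turns CGRfwd11098 in both phases. It also turns CGRfwd14669 in stationary phase, to -0.35 scaled log2 units, which did not pass. As shares of the summed excess, no strain difference of CGRfwd11098 passed.

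The comparison of phases asked whether SigH binding differs between late exponential growth and the onset of stationary phase. In unscaled values, no bound region passed the test between the phases. In the wild type the array medians were 0.63 and 0.50 log2 units in exponential and 1.51 and 0.62 in stationary phase, and all 27 regions had the higher mean in stationary phase, by a median of 0.61. In the deletion strain they were 2.38, 2.54 and 2.74 in exponential and 1.74, 4.30 and 2.75 in stationary phase, with a median difference of 0.38. Single arrays carried these medians. That of the wild type was 0.02 without its stationary replicate 1 and 1.14 without replicate 2, and that of the deletion strain was -0.28 without its stationary replicate 2 and 1.03 without replicate 1. The stationary arrays of the deletion strain differed more among themselves (SD 1.29, n = 3) than those of the exponential phase (SD 0.18, n = 3).

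By limma, 0 of 27 regions passed in the wild type, in the deletion strain and in their average, and 0 had an unadjusted p under 0.05 in any of these. Exact two-sided permutation tests of the array medians gave p = 0.667 in the wild type, p = 0.700 in the deletion strain and p = 0.579 over both, where the smallest possible values were 0.333, 0.1 and 0.00794. The direction in the deletion strain differed between slides. On slide 1 all 27 regions were lower in stationary phase, by a median of -0.68 log2 units from 1 array against 1. On slide 2 all 27 were higher, by 0.89 from 2 arrays against 2. That rise was carried by stationary replicate 2, whose array median was 4.30. Stationary replicate 3, with 2.75, lay near the exponential arrays of the slide, with 2.54 and 2.74. In the wild type the median difference on slide 1 was 0.13, with 21 regions higher and 6 lower. With slide as a fixed block 0 regions passed in any of the 3 comparisons (limma, 0 at an unadjusted p under 0.05). Without deletion, stationary replicate 1, 1 region passed in the average of the strains (limma adjusted p = 0.0314).

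Relative to the other regions of the same array, CGRfwd14669 was higher and CGRfwd11098 lower in stationary than in exponential phase in the wild type. The value of CGRfwd14669 was 0.21 and 0.23 log2 units on the 2 exponential arrays, below the array medians of 0.63 and 0.50, and 2.37 and 0.83 on the 2 stationary arrays, above the medians of 1.51 and 0.62. As a multiple of the array median it was 0.399 ± 0.0858 in exponential and 1.45 ± 0.172 in stationary phase (SD, n = 2 each). On the 6 deletion arrays the multiple was between 1.12 and 1.34. For CGRfwd11098 the multiple was 3.37 ± 0.18 in exponential and 2.18 ± 0.20 in stationary phase in the wild type (SD, n = 2 each). After scaling of the arrays to the same median, CGRfwd11098 changed by -2.35 scaled log2 units in the wild type (limma adjusted p = 7.39e-07). As a share of the summed excess it changed by -0.78 (limma adjusted p = 0.00864). Unscaled it went the other way, by 0.36 log2 units, and did not pass (limma adjusted p = 0.745). The scaling divides log2 values and so lowers strong regions of arrays with a high median. The rise of CGRfwd14669 on the scaled arrays was 2.08 scaled log2 units (limma adjusted p = 1.27e-08), whereas unscaled it was 1.38 log2 units and did not pass (limma adjusted p = 0.745). Over the 25 alternatives that gave a value for CGRfwd14669, normexp not among them, the rise lay between 0.60 and 2.26 in the units of each alternative. On the scaled arrays 5 regions were higher and 5 lower in stationary phase in the wild type, 5 and 3 in the average of the strains, and 0 and 0 in the deletion strain (limma, 0 at an unadjusted p under 0.05). The choice to describe CGRfwd14669 was made after its values were seen.

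**Figure D3:**
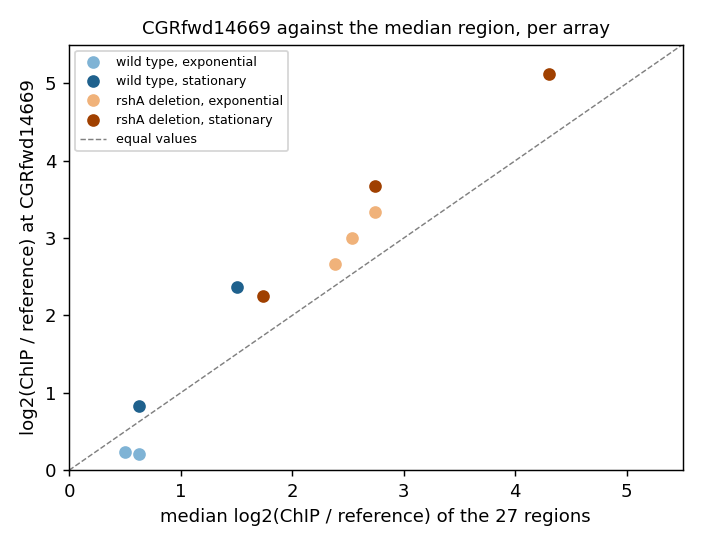
Log2 ratio of ChIP to reference signal at CGRfwd14669 (vertical axis) against the median of the 27 bound regions on the same array (horizontal axis), 1 point per array, with a dashed line where both are equal. The 2 exponential wild-type arrays lie below the line, at 0.21 and 0.23, and the 2 stationary wild-type arrays and the 6 deletion arrays lie above it.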

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

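The tests of a mislabelled sample, of slides, of the reference signal and of the immunoprecipitation yield at CGRfwd14669 were chosen after the results were seen. The counts over other splits of the arrays, the spread of excess enrichment between arrays and the check in the reverse tiling were set before.

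Enrichment also appeared at probes outside the forward tiling. Of the gene-numbered probes, 29 had a mean of at least 2-fold over the 4 groups (limma, adjusted p below the threshold), and 2 of the 15 CGRic probes did. The strain effect differed between phases at 3 regions once arrays were scaled to one median. The difference was 2.06 scaled log2 units at CGRfwd11098 (limma adjusted p = 0.000254), -1.88 at CGRfwd14669 (limma adjusted p = 6.39e-06) and -1.13 at 1 further region (limma adjusted p = 0.00134). Unscaled, 0 of 27 regions differed by limma, and as shares of the summed excess 4 did. These included CGRfwd14669, with -1.89 (limma adjusted p = 0.000621), and the further region, with -1.38 (limma adjusted p = 0.0116), but not CGRfwd11098, with 0.40 (limma adjusted p = 0.317).

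Among 100 splits of the 10 arrays into 6 and 4, with the real one included, 4 called as many regions as the split by strain, which called all 27, and the highest other split also called 27. That share lay below the preset limit of 5 in 100. It does not exclude chance, because the count was at its ceiling, 6 of the other splits called at least 5 regions, and the splits take no account of slides. The 3 splits with 27 were close to real structure. One exchanged deletion, stationary replicate 1 for wild type, stationary replicate 1. Another parted the 4 arrays of slide 2 from all others, and so followed the slides. The third put the wild type together with 2 deletion arrays of different slides. Within slide 1 all 27 regions were higher in the deletion strain, by a median of 1.88 log2 units in exponential and 1.17 in stationary phase, and with slide as a fixed block the averaged strain difference had a median of 1.499 log2 units with 0 regions past the threshold (limma, 12 at an unadjusted p under 0.05). For the phases over both strains, the real split called 0 regions, a count that 100 of 100 splits reach by necessity, so the splits say nothing about chance. The highest other split called 27. The 4 other splits with at least 5 regions all put 4 or 5 of the 6 deletion arrays on the same side. They also put 3 or 4 of the 4 arrays of slide 2 on the same side, so they cannot tell strains from slides. For the phases in the deletion strain, 10 splits of the 6 arrays are too few for a share under 0.05. The real split called 0 regions and the highest other 0, with 10 of the 10 splits at that count.

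The wild-type stationary arrays differed from each other, with a median region of 1.51 log2 units on replicate 1 and 0.62 on replicate 2. A sample of the deletion strain in place of replicate 1 is argued against by the deleted probes. Their ChIP signal there lay 0.41 log2 units above the mean of the other 3 wild-type arrays. That value is no independent check, since the probes were picked with this array counted as wild type. With a deletion sample there, the deleted gene would not have parted the arrays by these labels, whereas 3 probes did, by at least 4.90 log2 units in the reference channel. A uniformly higher yield of the immunoprecipitation remains a candidate explanation. The excess over background differed between the 2 arrays by a median of 2.02 log2 units, with an SD over the regions of 0.301, against 0.499 between the exponential wild-type arrays. Region values on those exponential arrays went down to 0.08 and 0.23 log2 units, and ratios of such small excesses are noisy. The comparison was therefore lenient towards a uniform yield. A slide effect cannot be told apart from a higher yield, since the slide of replicate 1 held 0 other arrays.

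The reference signal was low at the bound regions, although reference DNA was not immunoprecipitated. Dye normalization is argued against, because the raw reference signal at the summits already lay at -2.32 log2 units relative to the array median on average over the 6 deletion arrays. Competition of ChIP and reference DNA for the same spots stays open. The ChIP channel rose by 22.7% of the log2 ratio there, which restates the low reference signal and decides nothing. No biological explanation was tested.

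The relative rise of CGRfwd14669 in the wild type in stationary phase was weighed against 3 technical explanations. A uniformly higher yield is argued against by shares of the summed excess, which remove it and where the rise was 2.26 log2 units, and by wild type, stationary replicate 2, whose median was like those of the exponential arrays and whose value stood 0.871 array medians above the higher of them. Faulty forward probes are argued against by the reverse tiling, where the same region rose by 0.858 array medians. A slide effect is argued against because arrays of the same phase on different slides differed by 0.121 and 0.244 array medians, while the 2 phases on slide 1 differed by 0.871, although from the same pair of arrays as above. A change of SigH binding at this place relative to the other regions at the onset of stationary phase stays open as a hypothesis, on 2 arrays against 2, for a region picked in these data for its rise.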

How the results depend on the processing

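The values of raw signals, without dye normalization, for the share of summed excess and without deletion, stationary replicate 2 together with wild type, stationary replicate 1, were added after the results were seen.

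Only rescaling of the arrays called any region lower in the deletion strain, and several alternatives called 0. Where no cause is named, the cause was not tested. Gene lists and motif were not run. The removal of dim probes left 26 of the 27 regions. It lowered the strain difference of CGRfwd11098 to 2.21 (exponential) and 1.67 (stationary).

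Normexp failed on these arrays, and its values set no limit on the results. It fitted a mean background of 30511 to 43322 in the reference channel, where the measured local background was 39 to 62, and on 9 of 10 arrays it left at most 0.0978 log2 units between dim and bright spots (the lowest and highest 1% set aside), with their order kept. With it, 15 bound regions were called (7 of them among the 27), 38 and 8 in the wild type in exponential and stationary phase and 25 and 29 in the deletion strain, and the strains differed at 1 region in exponential phase, 0 in stationary phase (limma, 4 at an unadjusted p under 0.05) and 2 on average. The reference signal of the deleted probes then differed by 0.05 log2 units (0.048, exact permutation p = 0.7) in place of -7.49, whereas the raw signals differed by -6.76. Without dye normalization 14 regions passed between the strains in stationary phase. A minimum mean of 1.5 log2 units gave 13 regions and one of 1.5-fold gave 43. At least 5 probes per region gave 8 over all arrays, 22 in the deletion strain in exponential and 26 in stationary phase.

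With arrays scaled to one median, 17 regions differed between the strains in exponential and 14 in stationary phase, 10 between the phases in the wild type, 8 between the phases on average and 3 in the strain effect between phases. CGRfwd11098 then had strain differences of -3.09, -1.03 and -2.06 scaled log2 units in exponential phase, stationary phase and on average, and a phase difference of -2.35 in the wild type. The strain difference of CGRfwd14669 in stationary phase was -0.35 scaled log2 units. By construction this scaling divides log2 values, so a shared fold lowers strong regions of arrays with a high median. As shares of the summed excess, 8 and 5 regions differed between the strains in exponential and stationary phase and 13 on average, 5 between the phases in the wild type, 5 on average and 4 in the strain effect. CGRfwd11098 then had -0.19 between the strains in exponential phase and -0.78 between the phases in the wild type.

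With a fit to only the groups compared, 0 regions differed between the strains in stationary phase (limma, 5 at an unadjusted p under 0.05), and with trend and robust variance 9 did. Among the 50 regions of any single group, all called in the deletion strain, 41 differed on average, a count that this choice inflates. With slide as a fixed block 0, 0 and 0 regions differed between the strains in exponential phase, stationary phase and on average (limma, 1, 1 and 12 at an unadjusted p under 0.05), and as a random block 11 did in stationary phase. The replicate number as a random block left 26, 23 and 27.

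With single arrays or the pair named above left out, where a lone array is assumed to vary like the other groups, the counts lay between 19 and 33 for all regions, 0 and 12 for the wild type in stationary phase, 0 and 1 for it in exponential phase, 13 and 38 for the deletion strain in exponential phase and 34 and 59 in stationary phase. The strains differed at 0 to 33 regions in exponential phase, 0 to 32 in stationary phase and 19 to 33 on average, and the phases at 0 to 1 on average. With single arrays left out, the median strain difference was 1.88 to 2.10 in exponential phase, 1.16 to 2.41 in stationary phase and 1.604 to 2.18 on average, the phase difference 0.02 to 1.14 in the wild type and -0.28 to 1.03 in the deletion strain, and the difference of strain effects -0.89 to 0.43.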

Other observations

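The values here were looked at after the data were seen.

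A further 23 regions were called in the deletion strain in 1 phase or both but not over all arrays. Their median enrichment was 1.29 ± 0.08 log2 units in the deletion strain in exponential phase and 1.74 ± 1.12 in stationary phase (SD of array medians, n = 3 each). In the wild type it was 0.18 ± 0.03 in exponential and 0.57 ± 0.32 in stationary phase (n = 2 each). The group mean was above 0 in the wild type at 20 of the 23 regions in exponential phase and at all 23 in stationary phase, and it reached 2-fold at 0 and 1 of them. Because these regions were picked in the deletion strain, the gap between the strains is inflated by the choice. Tested together with the 27 others, 41 of 50 regions were higher in the deletion strain on average over the phases and 0 were lower (limma).

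The order of the 27 regions by enrichment was much alike in all groups. Spearman's rho across regions, which are not independent replicates, lay between 0.784 and 0.920 for the 6 pairs of groups. The lowest was between the wild type in exponential and the deletion strain in stationary phase, and the highest between the 2 phases of the deletion strain.

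The 29 enriched gene-numbered probes held 6 pairs of consecutive numbers, where 10000 random draws of as many probes gave 0.244 pairs on average and 3 at most. All 29 reached 2-fold as group means in both phases of the deletion strain, 11 did in the wild type in stationary phase and 3 in exponential phase. The forward probes outside the 27 regions that reached 2-fold numbered 365 on deletion, stationary replicate 2 and 0 to 62 on the other arrays.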
